A study of Homo sapiens with 25 samples.

How the data were processed

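RNA from cultured human coronary artery endothelial cells was labelled with biotin and hybridised to Affymetrix GeneChip arrays, 1 array for each of 25 samples in 5 groups of 5. Per the labels, the cells were used at passages 3 to 6, were plated 24 h before exposure in medium with 5% serum, were exposed for 16 to 24 h, and gave 1 µg of total RNA for each labelling reaction. The submitters' processing notes name the genome build hg19 and no other step, so the background correction, the normalization between arrays and the summarization of probes by the authors are not known.

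The deposited table holds log2 values of 28829 probe sets in the 25 samples, each relative to the median of the same probe set over all samples: every probe set has a median of 0 within a tolerance of 1e-06. No absolute signal is therefore left in the table, and neither a filter on dim genes nor a comparison of levels between genes could be made. The log base and the sign of the values are not stated; base 2 and positive for higher expression were assumed. Array medians ran from -0.0706 to 0.106 and the SD over probe sets of an array from 0.138 to 0.329. For arrays, precision is limited by their number, 5 per group. Probe sets were paired with gene symbols through the platform's annotation: 19291 probe sets had 1 symbol, 1735 had several and 7803 had none. Those with 1 symbol gave 18372 genes, of which 682 had more than 1 probe set, and 19260 of these probe sets had a gene identifier found in the reference gene table. A single probe set with the value 0 on 24 arrays was left out. For a gene with several probe sets their mean was used, because the rule chosen before the data were examined, the probe set with the highest mean, has no meaning in centred values. That rule was run as written as an alternative. The probe sets without 1 gene symbol were tested separately and were not used for the comparisons of genes.

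The description names of 8 arrays, replicates 4 and 5 of the apoA-I, PBS, rHDL and SUV groups, carry the prefix W, which the labels do not explain. The 17 other arrays, all 5 of native HDL among them, lack it. The prefix was treated as a possible batch. Genes were tested with limma 3.58.1 in R 4.3.3 on all 25 arrays, with group and prefix as additive terms, moderated variances (19 residual and 7.09 prior degrees of freedom), two-sided tests and the Benjamini-Hochberg adjustment at 0.05 within each comparison. Each agent was compared with PBS (4 comparisons), agents were compared with each other (4 comparisons), and the departure from additivity was the log2 effect of rHDL minus the effects of apoA-I and SUV. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. The fits were tested on simulated data with 200 changed genes: between 86% and 89% of genes changed by 0.5 log2 and between 99% and 100% of those changed by 1 log2 were recovered, with 5% to 5.91% false calls. The simulated noise was independent between genes, whereas the first component of the real residuals held 36.9% of their variance. These rates therefore need not carry over to the real arrays.

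Before the data were examined, 22 gene lists were fixed: cholesterol synthesis and uptake (SREBP-2 targets), fatty acid synthesis and desaturation (SREBP-1 targets), sterol efflux and LXR targets, fatty acid oxidation and PPAR targets, adhesion molecules and NF-kB cytokines, interferon-stimulated genes, the NRF2 oxidative stress response, metallothioneins, the unfolded protein response and ATF4 targets, the heat shock response, hypoxia and glycolysis, flow-responsive KLF2/KLF4 genes and vasodilators, S1P and HDL receptors and signalling, coagulation and fibrinolysis, angiogenesis and tip cell genes, TGF-beta targets and extracellular matrix, cell cycle and proliferation, p53 targets and apoptosis, immediate early genes, lysosome and autophagy, oxidative phosphorylation, and cytosolic ribosomal proteins. Another 9 lists held markers of endothelial cells, smooth muscle cells and pericytes, fibroblasts, monocytes and macrophages, lymphatic endothelial cells, T and B lymphocytes, red cells and platelets, hepatocytes, and epithelial cells. Lists were tested with camera of limma with a preset correlation of 0.01 between genes and the Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Members of a list were also counted after an adjustment over the list alone. The error of a list's median is the SE of the difference between groups of the list medians per array, with the prefix as a term.

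Genes named in the text were chosen by a rule fixed at the same time. It takes, for each agent against PBS, the 8 largest rises and the 8 largest falls among genes past the threshold in which all 5 agent arrays lay on the same side of the mean of the PBS arrays with the same prefix status. It adds up to 4 members of each list with the smallest p, and 17 genes fixed by name. For comparisons between agents and for additivity the rule takes the 5 largest rises and the 5 largest falls, and for cell type markers the members past the threshold. Genes named outside this rule are marked in the text as chosen after their values were seen.

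Alternatives left out the prefix term, added the replicate number as a block, used the arrays without or with the prefix alone, fitted only the groups compared, tested probe sets singly, normalized by quantiles, centred each array on its median, used a trended and robust variance model, used array weights, and left out each array in turn. Added after the data were seen were a covariate for array-wide background (the median over 339 olfactory receptor genes of each array, genes that endothelial cells are not known to express) and a fit without rHDL replicate 4 and apoA-I replicate 4. The probe set with the highest mean, fixed beforehand as the main rule and then replaced, was also added as an alternative. The overlap of calls between agents, which share the PBS arrays, was set beside 100 simulations of unchanged groups against the same controls and beside 20 splits of the controls into separate sets. Other splits of the arrays into groups of the same sizes were counted for every comparison, 100 each with the real one. Alternatives that need absolute levels, linear values or the 3' and 5' control probe sets were not run.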

Results

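Human coronary artery endothelial cells (HCAEC), primary cells of the lining of the coronary arteries, were profiled on 25 arrays after exposure to components of high-density lipoprotein (HDL). All arrays are labelled as these cells, although the growth protocol of the labels also names endothelial cells of the umbilical vein. Control cells received PBS, and the other 4 groups received native HDL from human plasma (1 mg/ml of total protein), reconstituted HDL (rHDL, apolipoprotein A-I at 1 mg/ml with the phospholipid PLPC, a palmitoyl-linoleoyl phosphatidylcholine), lipid-free apolipoprotein A-I (apoA-I, 1 mg/ml), or small unilamellar vesicles of PLPC (SUV, 3 mmol/L PLPC). Every group had 5 arrays. The doses matched apoA-I between rHDL and lipid-free apoA-I, but the PLPC concentration of rHDL was not given and native HDL was dosed by total protein, so that lipid was not matched between the agents. Effects are given as log2 fold changes ± SE with n = 5 arrays per group, from deposited values that were centred on each probe set's median and whose log base and sign were assumed. Values within the arrays without the W prefix (3 per group, 5 of native HDL) and with it (2 per group) follow the pooled ones where both exist; native HDL had no array with the prefix. Genes named for the largest changes against PBS lay on one side of the prefix-matched PBS mean in 5 of 5 agent arrays, which was not required of genes named between agents or for additivity.

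The series asked how each agent changed gene expression against PBS. Of 18372 genes tested with limma, 1811 changed under rHDL (824 higher, 987 lower), 1220 under SUV (593 higher, 627 lower), 788 under native HDL (345 higher, 443 lower) and 46 under apoA-I (18 higher, 28 lower). Changes of at least 1.5-fold were seen for 264, 145, 106 and 11 of these genes. Without PBS replicate 2, PBS replicate 3, native HDL replicate 4 or native HDL replicate 5 the count for native HDL was 456, 472, 505 or 521. In the arrays without the prefix alone 992 genes changed under rHDL, 965 under SUV, 638 under native HDL and 11 under apoA-I, and in those with it 213 under rHDL and 74 under SUV. After quantile normalization the balance turned to 1266 higher and 954 lower genes for native HDL and to 869 higher and 734 lower for rHDL. The count for native HDL was 2220 after this normalization, 3153 with array weights, 1609 with only the groups compared in the fit and 1659 with the olfactory receptor covariate. With quantile normalization (1603 for rHDL, 1793 for SUV), with array weights (2346 for rHDL, 1467 for SUV) and with only the groups compared (1214 for rHDL, 1271 for SUV) it was the highest of the 4 agents, so that the order of the agents by count was not fixed. The median SE of a gene was 0.08 to 0.09 log2. Fixed gene lists called by camera numbered 11 for rHDL, 7 for SUV, 10 for native HDL and 10 for apoA-I, of which 7, 4, 3 and 1 were called under every alternative run. Other splits of the same arrays called as many lists in 37, 36, 10 and 16 of 100, so that the number of lists was not a result in itself. The members of each list and its shift are therefore given list by list. Single lists were not all rare among the splits either. The share of splits with a median shift as large was under 0.05 for 7, 6, 7 and 3 of the called lists, in the same order. It was largest for hypoxia under rHDL (16 of 100), cell cycle under SUV (14), cholesterol under native HDL (20) and heat shock under apoA-I (43).

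**Figure D1:**
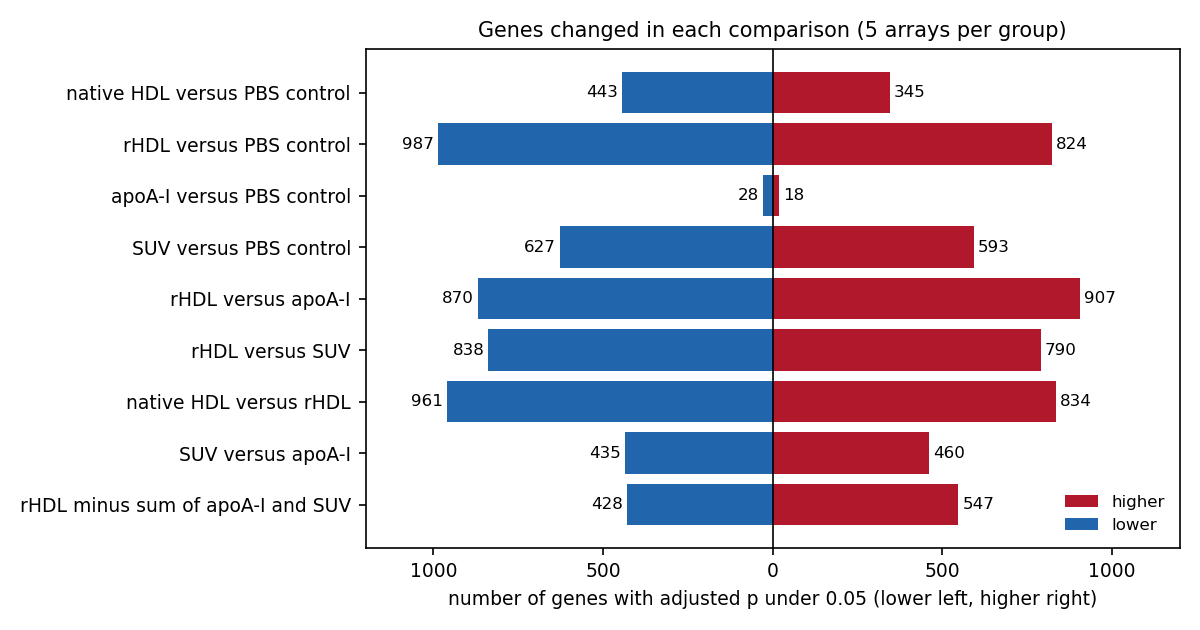
Number of genes with an adjusted p under 0.05 in each comparison, lower to the left and higher to the right, with 5 arrays per group. The bars for apoA-I against PBS hold 28 lower and 18 higher genes, and those for rHDL against PBS hold 987 lower and 824 higher genes.

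Native HDL lowered interferon-stimulated and inflammatory transcripts and raised a set of genes led by CYP1A1, a cytochrome P450 that oxidises foreign compounds. IFI44L fell by 2.75 ± 0.28 log2 (adjusted p = 2.73e-07; -2.84 without the prefix) and MX1, an antiviral GTPase, fell by 2.25 ± 0.21 (adjusted p = 8.51e-08; -2.30). IFI44, IFIT1, MX2, CXCL10, OAS1 and OAS2 fell by between 1.83 and 2.03. CYP1A1 rose by 2.45 ± 0.13, or 5.47-fold (adjusted p = 1.53e-12; 2.51). NMRAL2P rose by 0.91 ± 0.10, TIPARP, an ADP-ribosyltransferase, by 0.87 ± 0.09, the decoy receptor TNFRSF10D by 0.84 ± 0.08, and ABCC3, SPRY2 and ALDH1A1 by 0.78, 0.73 and 0.73.

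Of the 24 interferon-stimulated genes measured, 21 fell under native HDL and 3 did not pass (23 fell when adjusted over the list alone). Their median was -1.35 ± 0.14 (-1.41 without the prefix; adjusted p = 3.16e-49, and 0.00168 with an estimated correlation). Adhesion molecules and NF-kB cytokines fell in 12 of 23 members (17 adjusted over the list alone), with a median of -0.34 ± 0.04 (-0.29 without the prefix; adjusted p = 2.16e-17, and 0.000429 with an estimated correlation). VCAM1, which holds leukocytes on the endothelium, fell by 1.26 ± 0.10 (adjusted p = 1.91e-09; -1.13 without the prefix), and the chemokines CXCL6, CCL20 and CXCL1 fell by 1.58 ± 0.12, 1.42 ± 0.11 and 0.58 ± 0.06. ICAM1 fell by 0.49 ± 0.11 (adjusted p = 0.0102). CXCL8 fell by 0.39 ± 0.10 (adjusted p = 0.0223), a call that ended in the arrays without the prefix (adjusted p = 0.0636), without PBS replicate 2 (0.0866) and without native HDL replicate 3 (0.0724). SELE (-0.27, adjusted p = 0.157) and CCL2 (0.03, adjusted p = 0.908) did not pass. NRF2 target genes rose in 4 of 18 members (9 adjusted over the list alone), with a median of 0.19 ± 0.05 (0.23 without the prefix; adjusted p = 2.09e-09, and 0.022 with an estimated correlation). The cystine transporter SLC7A11 rose by 0.43 ± 0.06, the quinone reductase NQO1 by 0.46 ± 0.07 and the ferritin chain FTL by 0.43 ± 0.07, while HMOX1 measured 0.46 ± 0.14 (adjusted p = 0.0583).

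Lipid genes moved in both directions under native HDL. In the cholesterol list EBP rose by 0.40 ± 0.06 and TMEM97 by 0.37 ± 0.08, 2 of 20 members (4 adjusted over the list alone). The list median was 0.12 ± 0.07 (0.16 without the prefix; adjusted p = 0.000163, but adjusted p = 0.491 with an estimated correlation). INSIG1 (0.17, adjusted p = 0.23) and SREBF2 (0.22, adjusted p = 0.104) did not pass, although INSIG1 passed without native HDL replicate 5 (adjusted p = 0.031). ABCA1 and ABCG1, the transporters that load HDL with cholesterol, fell by 0.47 ± 0.07 (adjusted p = 3.65e-05) and 0.67 ± 0.11 (adjusted p = 0.000268), and LPCAT3 rose by 0.38 ± 0.07. SCARB1, the HDL receptor, rose by 0.27 ± 0.07 (adjusted p = 0.0181), a call that ended in the arrays without the prefix (adjusted p = 0.0543), without PBS replicate 2 (0.068) and without native HDL replicate 5 (0.0584). The sterol efflux list as a whole was not called (3 higher and 2 lower of 12, adjusted p = 0.696). NOS3, the endothelial nitric oxide synthase, rose by 0.46 ± 0.07 (adjusted p = 8.51e-05; 0.46 without the prefix) and SPNS2, a sphingosine-1-phosphate transporter, by 0.34 ± 0.07. The Notch target HES1 fell by 0.97 ± 0.14, UNC5B by 0.44 ± 0.07 and the plasminogen activator PLAT by 0.60 ± 0.10.

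A further 6 lists were called for native HDL with the preset correlation, and each lost the call with the estimated one. Fatty acid synthesis genes had a median of 0.08 ± 0.05 with no member past the threshold by limma (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0163, and adjusted p = 0.551 with an estimated correlation). Fatty acid oxidation genes had 2 members higher, CYP1A1 (2.45) among them, and 1 lower of 15. Their median was 0.09 ± 0.05 (adjusted p = 0.018, and adjusted p = 0.551 with an estimated correlation). Both calls ended without PBS replicate 1 (adjusted p = 0.0506 for each) and without native HDL replicate 3 (0.0874 and 0.0642). The oxidation list was not tested without CYP1A1. The unfolded protein response list had 2 of 26 members higher, CRELD2 (0.50 ± 0.09) and PDIA4 (0.31 ± 0.07), and a median of 0.05 ± 0.04 (adjusted p = 0.018, and adjusted p = 0.551 with an estimated correlation). Its call ended without PBS replicate 1 (0.0628) and without native HDL replicate 1 (0.0939). Angiogenesis genes had 9 members lower and 2 higher of 27 and a median of -0.10 ± 0.03 (adjusted p = 0.00232, adjusted p = 0.491 with an estimated correlation, and 0.0735 without the prefix). Lysosome genes had 3 of 24 members higher and a median of 0.08 ± 0.03 (0.10 without the prefix; adjusted p = 0.000583, and adjusted p = 0.491 with an estimated correlation). Cell cycle genes had 3 of 33 members lower (13 lower and 1 higher adjusted over the list alone) and a median of -0.16 ± 0.07 (adjusted p = 0.000176, and adjusted p = 0.551 with an estimated correlation), but -0.09 in the arrays without the prefix (adjusted p = 0.15). Not called were metallothioneins, heat shock (1 lower of 13), hypoxia (1 higher of 23), flow-responsive genes (2 higher of 20), S1P and HDL receptors (2 higher of 14), coagulation (3 lower of 18), TGF-beta targets (2 higher and 1 lower of 26), p53 targets (2 lower of 19), immediate early genes (2 higher and 1 lower of 21), oxidative phosphorylation and ribosomal proteins, with adjusted p from 0.0652 to 1. KLF2, S1PR1, CAV1, VWF and ANGPTL4 did not pass (0.09, -0.17, -0.11, 0.14 and -0.02).

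rHDL raised adhesion, NF-kB and immediate early genes and cholesterol synthesis genes, and lowered cell cycle and interferon-stimulated genes. SELE, the endothelial adhesion molecule E-selectin, rose by 1.69 ± 0.10 (adjusted p = 6.29e-12; 1.92 without and 1.36 with the prefix), the signalling adaptor TRAF1 by 1.49 ± 0.11 (1.66 and 1.23). PTGS2, the inducible cyclooxygenase, rose by 1.47 ± 0.09 (adjusted p = 1.13e-11; 1.68 and 1.17). CYP1A1 rose by 1.62 ± 0.12 (1.63 and 1.59), TFPI2 by 1.56 ± 0.14, the orphan nuclear receptor NR4A3 by 1.53 ± 0.09, the haem oxygenase HMOX1 by 1.39 ± 0.13 and PMCH by 1.37 ± 0.13. GJA5, the arterial connexin, fell by 2.66 ± 0.12 (adjusted p = 6.1e-14; -2.47 and -2.95), IFI44L by 1.93 ± 0.27 (-2.19 and -1.54) and DHRS3, a retinaldehyde reductase, by 1.81 ± 0.12 (-1.67 and -2.03).

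Adhesion molecules and NF-kB cytokines rose in 13 of 23 members under rHDL and fell in 2 (14 and 2 adjusted over the list alone). Their median was 0.38 ± 0.04 (0.42 without and 0.31 with the prefix; adjusted p = 1.48e-14, and 0.00155 with an estimated correlation). TNFAIP2 rose by 0.92 ± 0.07 and the chemokine CCL20 by 1.02 ± 0.11 (adjusted p = 2.28e-07). The 2 members that fell, named after their values were seen, were the neutrophil chemokines CXCL1 (-0.39) and CXCL6 (-0.83). VCAM1 (0.13, adjusted p = 0.502; 0.32 and -0.16 by prefix), CXCL8 (0.16, adjusted p = 0.376) and CCL2 (0.01, adjusted p = 0.969) did not pass. ICAM1 rose by 0.38 ± 0.11 (adjusted p = 0.0253; 0.58 and 0.08 by prefix). The call ended with the prefix alone (adjusted p = 0.937) and without PBS replicate 2 (0.078), PBS replicate 3 (0.0765), rHDL replicate 1 (0.0602), rHDL replicate 3 (0.0889) or rHDL replicate 5 (0.0789). Immediate early genes, the first transcripts after a stimulus, rose in 13 of 21 members (15 adjusted over the list alone), with a median of 0.28 ± 0.04 (0.27 and 0.30 by prefix; adjusted p = 3.11e-18, and 0.00186 with an estimated correlation). EGR1 rose by 1.27 ± 0.08, ZFP36 by 0.96 ± 0.11 and ATF3 by 0.67 ± 0.08.

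Cell cycle genes fell in 30 of 33 members under rHDL (33 adjusted over the list alone), with a median of -0.51 ± 0.07 (-0.42 and -0.66 by prefix; adjusted p = 9.75e-36, and 0.00453 with an estimated correlation). PLK1 fell by 0.60 ± 0.07, cyclin A2 (CCNA2) by 0.54 ± 0.06 and the thymidylate synthase TYMS by 0.59 ± 0.08. Arrays with the prefix also had lower cell cycle transcripts than those without it across the groups, with 32 of 33 members lower and a median difference of -0.40. Interferon-stimulated genes fell in 20 of 24 members (23 adjusted over the list alone), with a median of -0.88 ± 0.14 (-0.96 and -0.65 by prefix; adjusted p = 1.69e-23, and 0.0143 with an estimated correlation). IFI44 fell by 1.71 ± 0.17, MX1 by 1.46 ± 0.20 and OAS3 by 1.05 ± 0.12.

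The cholesterol list rose in 15 of 20 members under rHDL (19 adjusted over the list alone), with a median of 0.47 ± 0.06 (0.54 and 0.36 by prefix; adjusted p = 2.01e-22, and 0.00691 with an estimated correlation). HMGCS1, which feeds the mevalonate pathway, rose by 0.88 ± 0.11, ACAT2 by 0.84 ± 0.11, INSIG1 by 0.76 ± 0.07 (adjusted p = 3.86e-08), EBP by 0.59 ± 0.06 and SREBF2, the transcription factor of the pathway, by 0.52 ± 0.07. Fatty acid synthesis genes rose in 8 of 15 members, ACSS2 by 0.86 ± 0.09 and LPIN1 by 0.62 ± 0.07 among them. Their median was 0.24 ± 0.05 (0.29 and 0.16 by prefix; adjusted p = 1.68e-09, but adjusted p = 0.0503 with an estimated correlation). In the sterol efflux list 3 members rose and 4 fell of 12, and the list was not called (adjusted p = 0.0719). ABCA1 fell by 0.96 ± 0.06 (adjusted p = 2.92e-11; -1.01 and -0.89), ABCG1 by 1.26 ± 0.10 and the LXR target MYLIP by 0.66 ± 0.09, while the cholesterol exporter NPC1 rose by 0.73 ± 0.08. SCARB1 rose by 0.23 ± 0.07 (adjusted p = 0.0253), a call that ended within either prefix set (adjusted p = 0.212 and 0.509) and without PBS replicate 2 (0.0668), PBS replicate 4 (0.0561), rHDL replicate 3 (0.0787) or rHDL replicate 5 (0.0658).

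Unfolded protein response and NRF2 genes also rose under rHDL, while the heat shock and metallothionein lists were not called. The unfolded protein response and ATF4 list rose in 14 of 26 members and fell in 1 (17 and 1 adjusted over the list alone). Its median was 0.32 ± 0.04 (0.30 and 0.27 by prefix; adjusted p = 9.31e-16, and 0.00817 with an estimated correlation). The stress transcription factor DDIT3 rose by 1.29 ± 0.14, CHAC1 by 1.12 ± 0.12, HERPUD1 by 0.84 ± 0.10 and the serine synthesis enzyme PHGDH by 0.72 ± 0.07. NRF2 targets rose in 10 of 18 members (11 adjusted over the list alone), NQO1 by 0.68 ± 0.07 and SLC7A11 by 0.41 ± 0.06. Their median was 0.30 ± 0.04 (0.37 and 0.20 by prefix; adjusted p = 3.25e-11, and 0.0072 with an estimated correlation). Hypoxia and glycolysis genes rose in 7 of 23 members, NDRG1 by 0.97 ± 0.06 and VEGFA by 0.36 ± 0.07. Their median was 0.10 ± 0.03 (0.10 and 0.03 by prefix; adjusted p = 0.000404, but adjusted p = 0.166 with an estimated correlation and 0.135 with the prefix alone). Lysosome genes rose in 6 of 24 members, SQSTM1 by 0.64 ± 0.07, with a median of 0.12 ± 0.03 (adjusted p = 7.33e-06, but adjusted p = 0.101 with an estimated correlation and 0.0778 with the prefix alone). Fatty acid oxidation genes had 3 members higher, CYP1A1 (1.62) among them, and 1 lower of 15. Their median was 0.10 ± 0.05 (adjusted p = 0.0106, but adjusted p = 0.309 with an estimated correlation, 0.253 with the prefix alone and 0.0669 without rHDL replicate 5). This list was not tested without CYP1A1.

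The remaining lists were not called for rHDL, with adjusted p from 0.227 to 0.914. Among flow-responsive genes 4 rose and 2 fell of 20, the anticoagulant receptor THBD by -0.57 ± 0.08. Coagulation genes had 5 higher and 3 lower of 18, with the clotting initiator F3 up by 0.77 ± 0.12 (0.60 and 1.03 by prefix). Angiogenesis genes had 7 higher and 6 lower of 27: the peptide APLN rose by 0.99 ± 0.08, and the Notch targets HEY2 and HES1 fell by 1.20 ± 0.13 (-0.88 and -1.67 by prefix) and 0.99 ± 0.14. The S1P and HDL receptor list had 3 members higher of 14, TGF-beta targets 1 higher and 2 lower of 26, p53 targets 1 higher (CDKN1A, 0.41 ± 0.08) and 1 lower of 19, heat shock genes 2 lower of 13 and metallothioneins 1 lower of 10. No member of the oxidative phosphorylation (27) or ribosomal protein (26) lists passed by limma, with the smallest p for SDHC (0.18, adjusted p = 0.167) and RPS16 (0.13, adjusted p = 0.23). NOS3 rose by 0.25 ± 0.06 (adjusted p = 0.013), without passing within either prefix set alone. KLF2, S1PR1, CAV1, VWF and ANGPTL4 did not pass (0.04, -0.03, 0.06, 0.06 and 0.03).

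Lipid-free apoA-I changed fewer genes than the other agents, and several of those it lowered encode inflammatory proteins. CCL20 fell by 0.90 ± 0.11 (adjusted p = 0.000178; -0.84 without and -0.99 with the prefix), TNFAIP6 by 0.80 ± 0.12 (-0.61 and -1.09) and PTGS2 by 0.70 ± 0.09 (adjusted p = 0.000327; -0.54 and -0.93). VCAM1 fell by 0.66 ± 0.09 (adjusted p = 0.000362; -0.47 and -0.94) and the interleukin receptor IL7R by 0.59 ± 0.10. CYP1A1 rose by 0.90 ± 0.12 (adjusted p = 0.000327; 0.96 and 0.80), and HERPUD1, ABCC3, SDF2L1 and NMRAL2P rose by 0.65 ± 0.10, 0.56 ± 0.08, 0.55 ± 0.08 and 0.53 ± 0.09. The count of 46 genes fell to 28 without apoA-I replicate 5, 28 without PBS replicate 4, 29 without apoA-I replicate 3 and 30 without PBS replicate 5. It was 11 in the arrays without the prefix and 0 by limma in those with it, where 1858 genes had an unadjusted p under 0.05. Array weights raised the count to 227 and quantile normalization to 99.

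Adhesion molecules and NF-kB cytokines fell in 6 of 23 members under apoA-I (17 adjusted over the list alone), with a median of -0.33 ± 0.04 (-0.31 and -0.38 by prefix; adjusted p = 9.79e-30, and 1.01e-05 with an estimated correlation). CXCL1 fell by 0.45 ± 0.06 (adjusted p = 0.000327). ICAM1 (-0.25, adjusted p = 0.75), SELE (-0.38, adjusted p = 0.169), CXCL8 (-0.37, adjusted p = 0.129) and CCL2 (-0.01, adjusted p = 0.981) did not pass. The unfolded protein response list rose in 6 of 26 members (9 adjusted over the list alone), HERPUD1 and SDF2L1 among them. Its median was 0.13 ± 0.04 (0.15 and 0.16 by prefix; adjusted p = 1.62e-12, but adjusted p = 0.0576 with an estimated correlation). Interferon-stimulated genes had a median of -0.42 ± 0.14 (-0.33 and -0.51 by prefix; adjusted p = 6.7e-18, but adjusted p = 0.0808 with an estimated correlation). None of the 24 passed by limma over all genes, although 14 were lower when adjusted over the list alone, and IFI44 (-0.69, adjusted p = 0.0971) passed without apoA-I replicate 1 (adjusted p = 0.00552) and without PBS replicate 4 (adjusted p = 0.0247). Angiogenesis genes fell in 4 of 27 members, with a median of -0.09 ± 0.03 (-0.05 and -0.11 by prefix; adjusted p = 3.23e-08, but adjusted p = 0.0808 with an estimated correlation).

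A further 6 lists were called for apoA-I without a member past the threshold by limma, and none held with an estimated correlation. Cell cycle genes had a median of -0.13 ± 0.07 (adjusted p = 1.7e-11, but adjusted p = 0.164 with an estimated correlation), which was -0.03 without the prefix (adjusted p = 0.391) and -0.31 with it. The cholesterol list had a median of 0.10 ± 0.06 (0.14 and 0.06 by prefix; adjusted p = 0.000331, but adjusted p = 0.374 with an estimated correlation and 0.664 with the prefix alone). NRF2 targets had a median of 0.11 ± 0.04 (adjusted p = 0.00174, but adjusted p = 0.287 with an estimated correlation, 0.988 with the prefix alone and 0.068 without apoA-I replicate 1). Fatty acid synthesis genes had a median of 0.04 ± 0.05 (0.09 and -0.02 by prefix; adjusted p = 0.0412, but adjusted p = 0.647 with an estimated correlation). Heat shock genes had a median of -0.03 ± 0.02 (adjusted p = 0.0466, but adjusted p = 0.364 with an estimated correlation) and coagulation genes -0.03 ± 0.02 (adjusted p = 0.0268, but adjusted p = 0.324 with an estimated correlation). Each of these 3 calls also ended in several fits that left out a single array. Not called were sterol efflux, fatty acid oxidation (1 higher of 15, CYP1A1), metallothioneins, hypoxia, flow-responsive genes (1 lower of 20), S1P and HDL receptors, TGF-beta targets, p53 targets, immediate early genes, lysosome, oxidative phosphorylation and ribosomal proteins, with adjusted p from 0.23 to 0.983. ABCA1 (-0.05, adjusted p = 0.9), ABCG1 (-0.36, adjusted p = 0.262), SCARB1 (0.12, adjusted p = 0.844), INSIG1 (0.14, adjusted p = 0.823), SREBF2 (0.11, adjusted p = 0.866), HMOX1 (0.12, adjusted p = 0.883) and NOS3 (0.18, adjusted p = 0.565) did not pass. Neither did KLF2, S1PR1, CAV1, VWF and ANGPTL4 (0.01, -0.16, -0.05, 0.12 and -0.40).

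SUV, which hold phospholipid and no protein, lowered interferon-stimulated and inflammatory genes and raised cholesterol synthesis genes. IFI44L fell by 2.57 ± 0.27 (adjusted p = 1.98e-07; -2.75 without and -2.31 with the prefix), MX1 by 2.27 ± 0.20 (-2.38 and -2.10), DHRS3 by 2.10 ± 0.12 (adjusted p = 5.06e-12; -2.02 and -2.22) and CXCL10 by 1.97 ± 0.27 (-1.60 and -2.52). APLN rose by 1.10 ± 0.08 (adjusted p = 1e-10; 1.11 and 1.09), NMRAL2P by 1.09 ± 0.09, HMOX1 by 0.96 ± 0.13 (1.09 and 0.78), and TXNIP, an inhibitor of thioredoxin, by 0.92 ± 0.09. AKR1C3, MALL, RGS7BP and TM4SF18 rose by between 0.84 and 0.91. Interferon-stimulated genes fell in 20 of 24 members (22 adjusted over the list alone), with a median of -1.26 ± 0.14 (-1.34 and -1.24 by prefix; adjusted p = 3.86e-43, and 0.00335 with an estimated correlation).

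Adhesion molecules and NF-kB cytokines fell in 11 of 23 members under SUV and rose in 1 (14 and 1 adjusted over the list alone). Their median was -0.39 ± 0.04 (-0.42 and -0.35 by prefix; adjusted p = 1.76e-14, and 0.00141 with an estimated correlation). The chemokine CXCL6 fell by 1.76 ± 0.12 (adjusted p = 6.91e-11; -1.79 and -1.71), CXCL8 by 0.93 ± 0.09 (-0.75 and -1.20), VCAM1 by 0.89 ± 0.09 (-0.74 and -1.11), CXCL1 by 0.86 ± 0.06 and ICAM1 by 0.62 ± 0.11 (adjusted p = 0.000454). The member that rose, named after its value was seen, was the chemokine CX3CL1 (0.39). SELE (-0.02, adjusted p = 0.951) and CCL2 (0.01, adjusted p = 0.96) did not pass. NRF2 targets rose in 6 of 18 members (9 adjusted over the list alone), NQO1 by 0.65 ± 0.07 and FTL by 0.48 ± 0.07. Their median was 0.21 ± 0.04 (0.28 and 0.09 by prefix; adjusted p = 6.78e-08, and 0.0363 with an estimated correlation).

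The cholesterol list rose in 13 of 20 members under SUV (16 adjusted over the list alone), with a median of 0.44 ± 0.06 (0.42 and 0.43 by prefix; adjusted p = 3.98e-19, and 0.0176 with an estimated correlation). ACAT2 rose by 0.76 ± 0.11, EBP by 0.68 ± 0.06 (adjusted p = 2.47e-08), INSIG1 by 0.44 ± 0.07 and SREBF2 by 0.44 ± 0.07. Fatty acid synthesis genes rose in 8 of 15 members (9 adjusted over the list alone), ACSS2 by 0.64 ± 0.09 and the desaturases FADS2 and SCD by 0.56 ± 0.06 and 0.38 ± 0.06. Their median was 0.38 ± 0.05 (0.32 and 0.27 by prefix; adjusted p = 4.15e-09, but adjusted p = 0.0829 with an estimated correlation). ABCG1 fell by 0.98 ± 0.10 (adjusted p = 3.17e-07) and ABCA1 by 0.45 ± 0.06 (adjusted p = 1.87e-05), while NPC1 rose by 0.50 ± 0.08 and SCARB1 by 0.33 ± 0.07 (adjusted p = 0.00156). The sterol efflux list was not called (2 higher and 3 lower of 12, adjusted p = 0.981). Lysosome genes rose in 3 of 24 members, with a median of 0.12 ± 0.03 (0.16 and 0.06 by prefix; adjusted p = 0.00021, but adjusted p = 0.274 with an estimated correlation and 0.271 with the prefix alone). The cell cycle list had 2 of 33 members higher and a median of 0.09 ± 0.07 (0.14 and 0.04 by prefix; adjusted p = 0.00533, but adjusted p = 0.824 with an estimated correlation, 0.791 with the prefix alone, 0.125 after quantile normalization and 0.147 without PBS replicate 1).

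In lists not called for SUV, with adjusted p from 0.112 to 0.981, members moved both ways. NOS3 rose by 0.47 ± 0.06 (adjusted p = 1.75e-05; 0.49 and 0.44 by prefix) and PTGS2 fell by 0.61 ± 0.09 among flow-responsive genes (2 higher and 2 lower of 20). The chaperone HSPA5 fell by 0.50 ± 0.06 and MANF by 0.46 ± 0.07, while HERPUD1 rose by 0.47 ± 0.10 in the unfolded protein response list (5 higher and 5 lower of 26). S1PR1 fell by 0.25 ± 0.06 (2 higher and 2 lower of 14 in its list), PLAT fell by 0.71 ± 0.10 (1 lower of 18 coagulation genes) and CD34 rose by 0.62 ± 0.07 (3 higher and 5 lower of 27 angiogenesis genes). TGFBI fell by 0.44 ± 0.06 (1 higher and 2 lower of 26 TGF-beta targets) and PMAIP1 fell by 0.55 ± 0.12 (3 higher and 1 lower of 19 p53 targets). EGR1 rose by 0.52 ± 0.08 (4 higher and 2 lower of 21 immediate early genes). CYP1A1 rose by 0.73 ± 0.12 and ANGPTL4 fell by 0.65 ± 0.11 among fatty acid oxidation and PPAR targets (3 higher and 3 lower of 15). The zinc transporter SLC30A1 fell by 0.54 ± 0.08 (1 lower of 10 metallothionein list members), DNAJB1 rose by 0.40 ± 0.08 (1 higher of 13 heat shock genes) and ALDOC rose by 0.47 ± 0.10 (3 higher and 2 lower of 23 hypoxia genes). No oxidative phosphorylation or ribosomal protein gene passed by limma. KLF2 (0.07), CAV1 (-0.05) and VWF (0.15) did not pass.

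**Figure D2:**
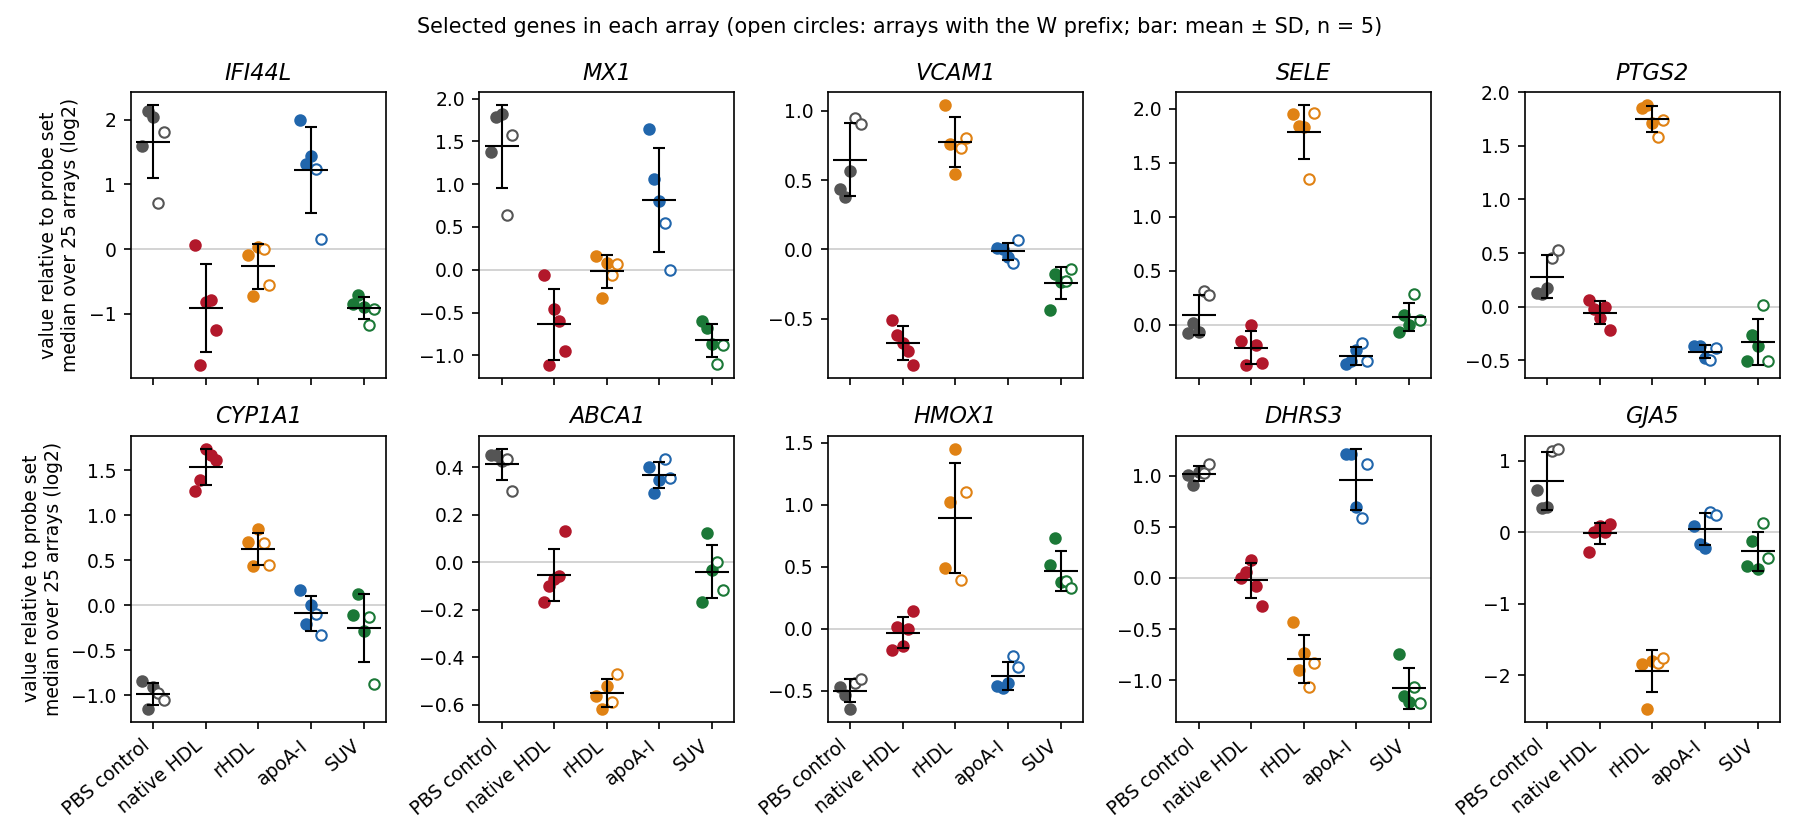
Values of 10 genes in each of the 25 arrays, as log2 relative to the probe set's median over all arrays, with open circles for arrays with the W prefix and bars for the mean ± SD of 5 arrays. SELE and PTGS2 stand high in the rHDL arrays alone, IFI44L and MX1 are lower under native HDL, rHDL and SUV than under PBS, and GJA5 is lowest under rHDL.

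**Figure D3:**
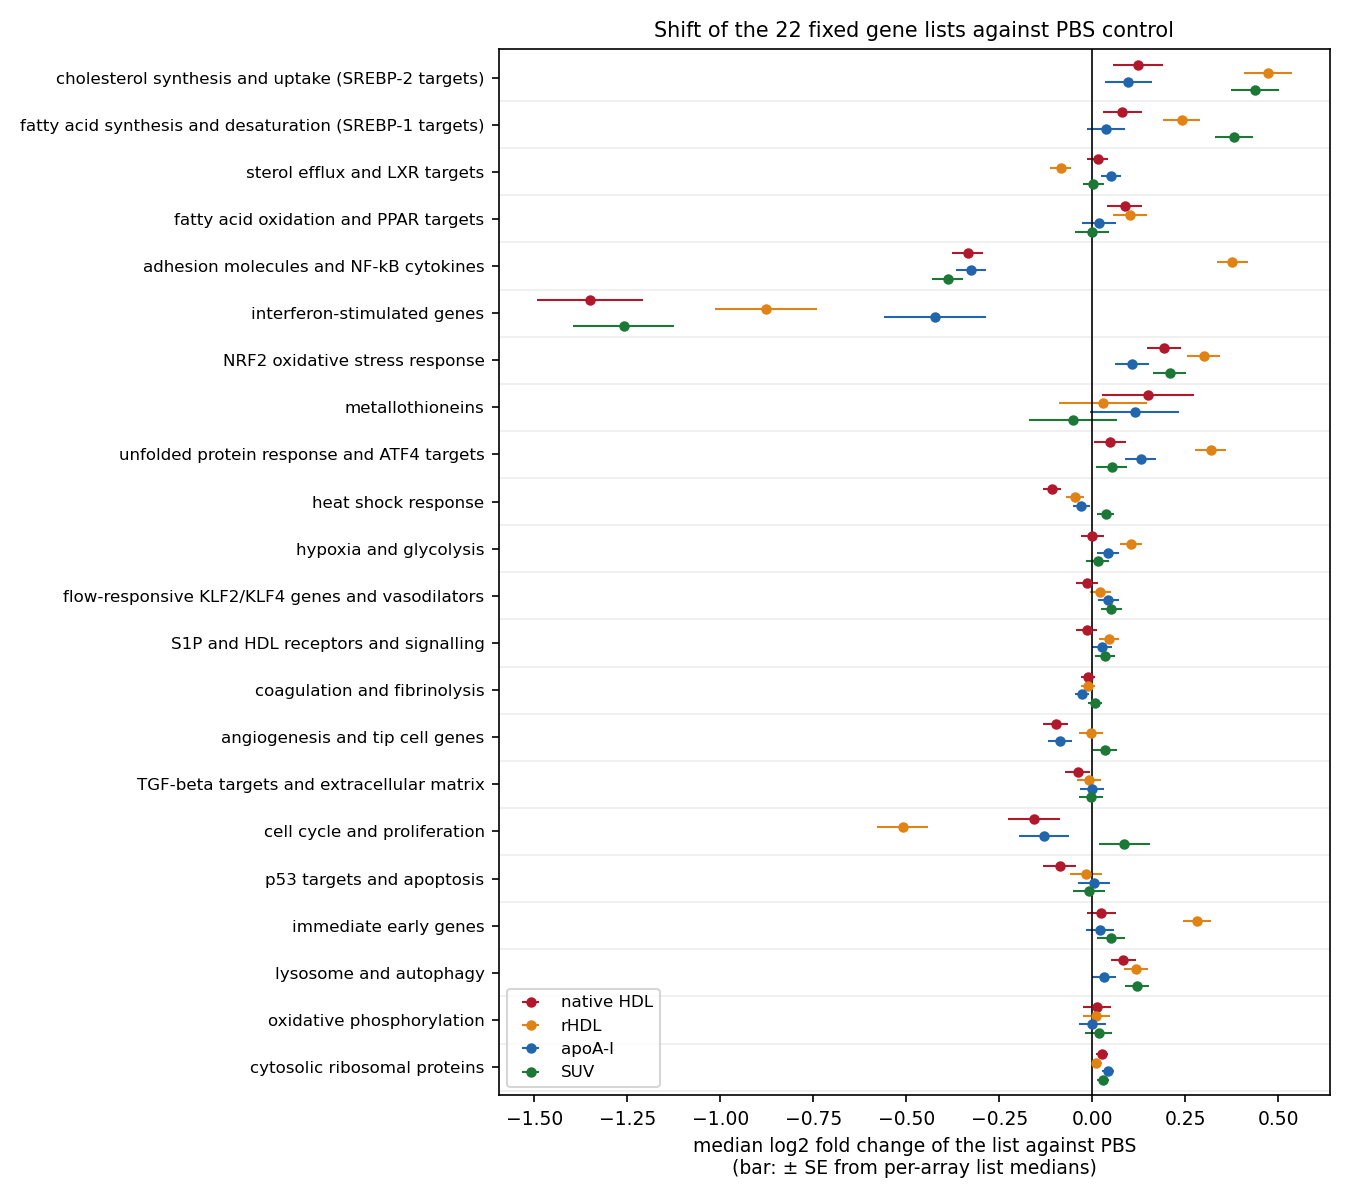
Median log2 fold change of the members of each of the 22 gene lists against PBS (points, with the SE of per-array list medians as bars) for the 4 agents. Adhesion molecules and NF-kB cytokines lie at 0.38 for rHDL and between -0.39 and -0.33 for the other agents.

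The cell type marker lists were measured beside these groups. Endothelial markers had a median of 0.09 under SUV, with EMCN and EGFL7 higher (0.43 and 0.25) of 13 (adjusted p = 0.0148, but adjusted p = 0.371 with an estimated correlation). They were not called under the other agents, where KDR fell under native HDL and rHDL (-0.25 and -0.32) and EMCN under rHDL (-0.39). Epithelial markers were lower under native HDL (median -0.16, adjusted p = 0.0421, but adjusted p = 0.443 with an estimated correlation) and SUV (median -0.10, adjusted p = 0.00453, but adjusted p = 0.163 with an estimated correlation). Their called members were KRT7 (-0.37 and -0.83) and, under SUV, KRT19 (-0.26). KRT7 also fell under rHDL (-0.996), where the list was not called (adjusted p = 0.132). Smooth muscle, fibroblast, monocyte and macrophage, lymphatic endothelial, lymphocyte, red cell and platelet, and hepatocyte lists were not called under any agent, with adjusted p of at least 0.0622. Single members that passed were TAGLN (0.52 under native HDL and 0.44 under rHDL), KCNMB1 (0.26 under rHDL), FAP (-0.39, -0.42 and -0.56 under native HDL, rHDL and SUV), COL1A2 (0.32 under SUV), RELN (0.78 under rHDL and 0.36 under SUV), SEMA3D (0.66 under rHDL), LYVE1 (0.49 under SUV), GP1BA (0.26 under rHDL) and IL7R (-0.68, -0.32, -0.59 and -1.12 under native HDL, rHDL, apoA-I and SUV). In called lists the median, the mean and the test had the same sign. Among uncalled gene lists the signs differed in 4 of 12 for native HDL, 3 of 11 for rHDL, 5 of 12 for apoA-I and 4 of 15 for SUV.

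Comparing rHDL with its protein asked what the particle changed at the same apoA-I dose. Against lipid-free apoA-I, 1777 genes differed (907 higher, 870 lower). PTGS2 was higher by 2.17 ± 0.09 (adjusted p = 5.99e-15; 2.22 and 2.10 by prefix), TFPI2 by 2.10 ± 0.14, SELE by 2.07 ± 0.10, CCL20 by 1.92 ± 0.11 and TRAF1 by 1.84 ± 0.11. GJA5 was lower by -1.99 ± 0.12 (adjusted p = 1.01e-11; -1.95 and -2.06 by prefix), DHRS3 by -1.76 ± 0.12, IFI44L by -1.50 ± 0.27, MGARP by -1.46 ± 0.11 and the growth factor BMP4 by -1.27 ± 0.15. ABCA1, which apoA-I left unshifted within its error, was lower under rHDL than under apoA-I by -0.92 ± 0.06 (adjusted p = 5.65e-11). The adhesion list was higher in 17 of 23 members, with a median difference of 0.65 ± 0.04 (adjusted p = 1.35e-34, and 3.27e-06 with an estimated correlation). The cholesterol list was higher in 12 of 20 (median 0.36; adjusted p = 1.79e-16, and 0.0289 with an estimated correlation) and the cell cycle list lower in 27 of 33 (median -0.40; adjusted p = 1.23e-21, and 0.0289 with an estimated correlation). Interferon-stimulated genes were lower in 13 of 24 (median -0.53; adjusted p = 1.2e-08, but adjusted p = 0.155 with an estimated correlation). Centring each array on its median changed the balance of calls to 1065 higher and 623 lower, and the olfactory receptor covariate to 1050 higher and 1424 lower. The total was 938 with only the groups compared in the fit and 1038 in the arrays without the prefix.

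Against SUV, whose lipid dose could not be matched, 1628 genes differed under rHDL (790 higher, 838 lower). PTGS2 was higher by 2.08 ± 0.09 (adjusted p = 1.75e-14; 2.19 and 1.91 by prefix), CCL20 by 1.98 ± 0.11, TSLP by 1.76 ± 0.10, SELE by 1.71 ± 0.10 and CCL5 by 1.67 ± 0.11. GJA5 was lower by -1.67 ± 0.12, RGS7BP by -1.21 ± 0.13, BMP4 by -1.12 ± 0.15, the histone gene H3C2 by -1.09 ± 0.14 and FAXDC2 by -1.05 ± 0.11. VCAM1 was higher under rHDL than under SUV by 1.02 ± 0.09 (adjusted p = 1.81e-08). The adhesion list was higher in 20 of 23 members (median 0.81; adjusted p = 8.51e-45, and 4.64e-07 with an estimated correlation). The unfolded protein response list was higher in 17 of 26 (median 0.35; adjusted p = 8.35e-19, and 0.00527 with an estimated correlation) and the cell cycle list was lower in all 33 (median -0.56; adjusted p = 1.28e-48, and 0.00141 with an estimated correlation). The cholesterol list (median 0.08, adjusted p = 0.0988) and the fatty acid synthesis list (median -0.00, adjusted p = 0.536) did not differ beyond the test's threshold.

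Native HDL and rHDL differed in 1795 genes (834 higher under native HDL, 961 lower). The total was 868 with only the groups compared in the fit, 2879 with array weights and 2775 with the olfactory receptor covariate. CCL20 was lower under native HDL by -2.44 ± 0.11 (adjusted p = 8.02e-14; -2.41 without the prefix), SELE by -1.96 ± 0.11, TRAF1 by -1.79 ± 0.12, PTGS2 by -1.78 ± 0.10 and TNFRSF9 by -1.76 ± 0.10. GJA5 was higher by 2.09 ± 0.13 (adjusted p = 8.68e-12; 2.03 without the prefix), BMP4 by 1.37 ± 0.16, ALDH1A1 by 1.19 ± 0.09, H3C2 by 1.14 ± 0.14 and HTR1B by 1.12 ± 0.08. The adhesion list was lower in 19 of 23 members (median -0.75; adjusted p = 1.62e-36, and 2.17e-06 with an estimated correlation). The cell cycle list was higher in 24 of 33 (median 0.34; adjusted p = 1.49e-22, and 0.0331 with an estimated correlation). The cholesterol list was lower in 11 of 20 (median -0.30; adjusted p = 3.25e-11, but adjusted p = 0.073 with an estimated correlation). Interferon-stimulated genes were lower in 7 of 24 (median -0.42; adjusted p = 3.3e-07, but adjusted p = 0.301 with an estimated correlation).

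SUV and apoA-I, the lipid and the protein of the particle, differed in 895 genes (460 higher under SUV, 435 lower; 568 in total without SUV replicate 1). IFI44L was lower under SUV by -2.14 ± 0.27, DHRS3 by -2.04 ± 0.12 (adjusted p = 9.76e-12; -2.07 without the prefix), MX1 by -1.63 ± 0.20, IFI6 by -1.41 ± 0.23 and the neurotrophin BDNF by -1.40 ± 0.12. TXNIP was higher by 0.92 ± 0.09, PEG10 by 0.90 ± 0.09, H3C7 by 0.89 ± 0.18, HMOX1 by 0.85 ± 0.13 and the small nuclear RNA gene RNU5F-1 by 1.08 ± 0.24 (1.49 and 0.48 by prefix). The H3C7 value leaned on apoA-I replicate 4, which lay at -1.75, with the other apoA-I arrays between -0.484 and 0.0477. Interferon-stimulated genes were lower in 19 of 24 members (median -0.83; adjusted p = 1.04e-27, but adjusted p = 0.0506 with an estimated correlation). Cholesterol genes were higher in 11 of 20 (median 0.32; adjusted p = 1.59e-14, but adjusted p = 0.078 with an estimated correlation). The adhesion list did not pass (median -0.04, adjusted p = 0.16).

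The effect of rHDL departed from the sum of the log2 effects of apoA-I and SUV in 975 genes, 547 above and 428 below it, with the lipid dose unmatched. CCL20 lay above the sum by 2.88 ± 0.15 (adjusted p = 1.25e-12; 2.79 and 3.01 by prefix) and PTGS2 by 2.78 ± 0.13 (adjusted p = 7.21e-14; 2.74 and 2.84). SELE lay above it by 2.09 ± 0.14, TFPI2 by 2.09 ± 0.19 and TNFAIP6, a hyaluronan-binding protein, by 2.02 ± 0.16. FAXDC2 lay below it by -1.41 ± 0.16, BMP4 by -1.36 ± 0.22, RGS7BP by -1.32 ± 0.18, CYP4X1 by -1.12 ± 0.16 and H3C2 by -1.11 ± 0.19. The adhesion list lay above the sum in 20 of 23 members (median 1.10 ± 0.06; adjusted p = 2.06e-56, and 6.77e-08 with an estimated correlation). Immediate early genes lay above it in 8 of 21 (median 0.20; adjusted p = 2.23e-12, and 0.0133 with an estimated correlation) and the cell cycle list below it in 23 of 33 (median -0.46; adjusted p = 1.25e-24, and 0.0236 with an estimated correlation). Interferon-stimulated genes lay above the sum in 12 of 24 (median 0.81; adjusted p = 2.1e-15, but adjusted p = 0.103 with an estimated correlation). The cholesterol list (median -0.01, adjusted p = 0.83) and NRF2 targets (median 0.01, adjusted p = 0.97) did not depart from it beyond the test's threshold.

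Native HDL and SUV shared 134 higher and 205 lower genes, with 10 in opposite directions. rHDL and SUV shared 250 higher and 223 lower genes, with 61 opposite, and native HDL and rHDL shared 103 and 156, with 56 opposite. Independent lists of these sizes would share 11.1 and 15.1, 26.6 and 33.7, and 15.5 and 23.8 genes. Simulated unchanged groups against the same PBS arrays shared a mean of 0, since groups without changes hold hardly any calls. That value does not show how far shared controls raise the overlap of real calls. With separate PBS arrays for each agent of a pair the medians of shared calls were 28 and 90 for native HDL with SUV, 97.5 and 87 for rHDL with SUV, and 32 and 70.5 for native HDL with rHDL. Such comparisons hold fewer PBS arrays, so that lost power may be part of the drop. Across genes, which are not independent replicates, the log2 effects of native HDL and SUV correlated with r = 0.658 (0.465 with separate controls, and 0.304 in the simulations that share controls). The covariance of the effects exceeded the simulated one by 0.0147 for this pair and 0.0121 for rHDL with SUV. The excess was 0.00884 for native HDL with rHDL, 0.00602 for native HDL with apoA-I and 0.00497 for apoA-I with SUV. It was lowest, 0.00266, for rHDL with apoA-I. The simulated groups were drawn without replacement from the residuals of the same arrays. The simulated r and covariance may therefore be too low, and the excesses too large. Covariances with separate controls, which use no simulation, were 0.0137, 0.0115, 0.00819, 0.00594, 0.00507 and 0.00281 in the same order. Of the fewer calls of apoA-I, 11 higher and 26 lower genes were shared with native HDL (0.338 and 0.675 for independent lists, 2.5 and 9 with separate controls). With SUV it shared 9 and 21, with 1 opposite (2 and 9 with separate controls), and with rHDL 15 and 11, with 10 opposite (4 and 2.5 with separate controls). For rHDL and apoA-I the correlation across genes, r = 0.319, was under the 0.391 of the simulations that share controls. Of 219 called results of named genes with a value in both prefix sets, 219 had the same sign in both. The rule for the largest changes against PBS asked for that agreement, and the other genes were picked on the same arrays. The agreement is therefore no independent support for the effects. Limma found 0 genes whose agent effect differed between the sets, with 740, 1320 and 685 genes at an unadjusted p under 0.05 for rHDL, apoA-I and SUV.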

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

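The tests of the prefix sets, of the PBS arrays, of the rHDL preparation and of rHDL replicate 4 were chosen only after the results they address had been seen. Among 515 groups of 5 values (array medians, list medians and named genes), 28 held a value far apart from the other 4, and chance alone gives about 25.8. The total thus lay near chance, which does not clear single arrays: apoA-I replicate 4 held 6 such values, native HDL replicate 3 held 5 and rHDL replicate 4 held 4. Array weights were lowest for rHDL replicate 4 (0.236) and apoA-I replicate 4 (0.473), and their SDs over probe sets were the highest (0.329 and 0.27). The deviations of these arrays from the fit correlated at 0.659. Apart from the weights and this correlation, all values here are log2 relative to the median over the arrays.

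The array median was lowest in SUV replicate 1 (-0.0706) and highest in rHDL replicate 4 (0.0755) of their groups. ApoA-I replicate 4 lay lowest of its group for cholesterol genes (-0.267), fatty acid synthesis genes (-0.102), p53 targets (-0.162), endothelial markers (-0.135), FICD (-0.205) and MALL (-0.389). Native HDL replicate 3 lay highest for angiogenesis genes (-0.0024), lysosome genes (0.11) and VWF (0.13), and lowest for CXCL8 (-0.261) and BDNF (-0.143). rHDL replicate 4 lay lowest for NRF2 targets (-0.0646), SELE (1.35) and BMP4 (-2.09). The other values lowest in their groups were NRF2 targets in PBS replicate 2 (-0.205), S1P and HDL receptors in native HDL replicate 1 (-0.0391), ABCA1 in PBS replicate 5 (0.298), ABCG1 in SUV replicate 3 (-0.648), PMCH in apoA-I replicate 1 (-0.335), GJA5 in native HDL replicate 1 (-0.272) and rHDL replicate 2 (-2.47), DDIT3 in native HDL replicate 4 (-0.76), DNAJB9 in rHDL replicate 3 (0.28), and IFI6 in PBS replicate 4 (0.164) and SUV replicate 4 (-1.18). NOS3 lay highest in rHDL replicate 3 (0.141). Among 9537 probe sets without 1 named gene, which the comparisons did not use, 39 changed under native HDL (13 higher, 26 lower), 151 under rHDL (85 higher, 66 lower), 1 under apoA-I (lower) and 99 under SUV (51 higher, 48 lower).

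Adhesion and NF-kB genes rose under rHDL and not under its lipid or its protein. With the olfactory receptor covariate for array-wide background the list median was 0.393 ± 0.0402. The olfactory receptor medians overlapped between rHDL (-0.084 to 0.21) and PBS (-0.1 to 0.111), so the covariate could hardly have moved the list. They show only that these genes did not set the groups apart. An origin in 1 prefix set is argued against by medians of 0.418 ± 0.0449 without and 0.313 ± 0.0732 with the prefix. PBS arrays out of place are argued against by medians of 0.649 against apoA-I and 0.809 against SUV, which use no PBS array. A substance carried by the rHDL preparation, such as endotoxin, cannot be told apart from the particle itself, since all 5 rHDL arrays received the preparation. That the assembled particle itself acts on these genes stays a hypothesis beside it.

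Interferon-stimulated genes fell under native HDL, rHDL and SUV. PBS arrays out of place are argued against by list medians of -0.918, -0.528 and -0.829 against apoA-I. With the background covariate the medians against PBS were -1.36, -0.842 and -1.22. Olfactory receptor medians of native HDL (-0.133 to 0.0106), rHDL (-0.084 to 0.21) and SUV (-0.161 to 0.0875) overlapped those of PBS (-0.1 to 0.111). The covariate could therefore hardly have moved the list, and this fit decides little. Both prefix sets held the fall, with -0.962 and -0.649 for rHDL and -1.34 and -1.24 for SUV. The values against apoA-I and within the prefix sets argue against misplaced PBS arrays and 1 prefix set as the whole cause, with limits. The prefix sets could not be compared for native HDL, and against apoA-I the list lost its call for rHDL and SUV with an estimated correlation. Nor do they single out a cause in the agents. An effect of phospholipid, which all 3 agents contain, is a candidate. That remains a hypothesis found and tested on the same data, no array separates lipid from the rest of native HDL, and lipid-free apoA-I also gave a list median of -0.423.

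Cell cycle genes fell under rHDL, in arrays where the prefix itself went with lower cell cycle genes. The prefix sets gave list medians of -0.42 ± 0.0657 without and -0.656 ± 0.129 with the prefix, so that neither set alone made the fall. With the background covariate the median was -0.497, but the olfactory receptor medians of rHDL and PBS overlapped, so that this fit could hardly have moved it. A single deviating array is argued against by -0.481 ± 0.0606 without rHDL replicate 4. An effect of rHDL on growth is a hypothesis that stays open beside a difference in cell density between the cultures, which no value in the table measures.

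Other splits of the same arrays, 100 for each comparison with the real one counted, do not measure chance alone. They ignored the prefix, and splits that mix differing groups carry a wider spread. The median of the others was 0 changed genes in every comparison. What they can show is whether a count as large can be called rare among them. It can for native HDL (788 genes; 1 split as large, highest other 0), rHDL (1811; 1, highest other 404), apoA-I (46; 2, highest other 2126), SUV (1220; 1, highest other 347), rHDL against apoA-I (1777; 3, highest other 3001), rHDL against SUV (1628; 2, highest other 2438), native HDL against rHDL (1795; 1, highest other 570), SUV against apoA-I (895; 2, highest other 1827) and additivity (975; 1 of 100 splits of 20 arrays, highest other 129). The highest other count for apoA-I was many times the real one and points to a structure of the arrays: its split set apoA-I replicates 3, 4 and 5 with PBS replicates 1 and 4 against the rest. The arrays of the first side had olfactory receptor medians from 0.0486 to 0.297, and the rest from -0.158 to -0.0248. The highest of the splits above the real count in 3 comparisons between agents put rHDL replicates 3 and 4 or apoA-I replicates 3 and 4 on the same side, across the prefix sets. For the number of called lists chance cannot be excluded: 10 splits gave as many as the 10 lists of native HDL (highest other 12), 37 as many as the 11 of rHDL (17), 16 as many as the 10 of apoA-I (17) and 36 as many as the 7 of SUV (13).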

How the results depend on the processing

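The olfactory receptor covariate and the fit without rHDL replicate 4 and apoA-I replicate 4 were chosen only after the results had been seen. The probe set with the highest mean was fixed beforehand as the main rule, and its use as an alternative was added later. Of 292 called results of named genes 0 changed sign, while 37 lost the threshold without some single array and 146 under some other alternative (of uncalled results 17 and 65 passed). The cause of the following moves by over 1.5 times was not tested, except that smaller sets of arrays hold fewer. Replicate numbers did not pair the arrays across all groups (12 of 50 same-numbered pairs correlated over 0.1, median -0.018). For apoA-I with rHDL, picked after the values were seen, all correlations were positive (0.576, 0.082, 0.277, 0.659 and 0.032 for replicates 1 to 5). Pairing between these groups is therefore not excluded. With the replicate block, rHDL against apoA-I gave 1600 genes in place of 1777 and additivity 861 in place of 975. Native HDL gave 307 in place of 788 and native HDL against rHDL 1077 in place of 1795, and no other count moved that far. Arrays without the prefix alone gave 992 genes for rHDL (1811 on all arrays), 11 for apoA-I (46), 1038 for rHDL against apoA-I (1777) and 492 for additivity (975). Arrays with it alone gave 213 for rHDL, 0 by limma for apoA-I (1858 at an unadjusted p under 0.05), 74 for SUV (1220), 143 for rHDL against apoA-I, 208 for rHDL against SUV (1628), 24 for SUV against apoA-I (895) and 28 for additivity. Only the groups compared gave 1609 for native HDL, 938 for rHDL against apoA-I, 881 for rHDL against SUV, 868 for native HDL against rHDL and 435 for SUV against apoA-I. Quantile normalization gave 2220 for native HDL (1266 higher and 954 lower, against 345 and 443) and 99 for apoA-I, and for rHDL against apoA-I 832 higher and 415 lower. Under quantile normalization native HDL came before SUV (1793) and rHDL (1603), unlike on the values as deposited. Median centring gave 562 higher and 328 lower for SUV against apoA-I (460 and 435). Array weights gave 3153 for native HDL (2346 for rHDL), 227 for apoA-I and 2879 for native HDL against rHDL. The olfactory receptor covariate gave 1659 for native HDL, 2775 for native HDL against rHDL and 1444 for SUV against apoA-I. Called lists numbered 3, 7, 1 and 4 for native HDL, rHDL, apoA-I and SUV with an estimated correlation, and 5 for native HDL and 2 for apoA-I with fry. Leaving out single arrays gave 456 (without PBS replicate 2) to 667 genes for native HDL, 28 to 58 for apoA-I and 568 (without SUV replicate 1) to 1201 for SUV against apoA-I. A filter on dim genes, a covariate from control probe sets and another pseudocount were not run, since the centred values hold no levels; signal over background was not known for any array.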

Other observations

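The tests of aryl hydrocarbon receptor and retinoic acid targets were chosen only after CYP1A1, TIPARP, DHRS3 and RARB had been seen to change and CYP1B1, CYP26A1, CYP26B1 and STRA6 had been seen not to pass. CYP1A1 rose under native HDL by 2.45, under rHDL by 1.62, under apoA-I by 0.90 and under SUV by 0.73, and TIPARP rose under native HDL (0.87) and rHDL (0.59) but did not pass under apoA-I (0.02) or SUV (0.10). Both are targets of the aryl hydrocarbon receptor, and a ligand carried by preparations from plasma may raise them. CYP1B1, another target, did not pass under native HDL (-0.04), rHDL (-0.03), apoA-I (-0.03) or SUV (0.04). Since the centred values hold no levels of CYP1B1, its lack of change cannot be weighed for or against such a ligand. Of 6 further targets measured, NQO1, which NRF2 also raises, is named above among NRF2 targets, and the values of the others had not been seen. Under native HDL 1 of the 6 was higher (NQO1, median of the 6 0.0824) and under rHDL 3 were (NQO1, SLC7A5 and NEDD9, median 0.309). None was higher under apoA-I by limma (median 0.082) and 1 was under SUV (NQO1, median 0.075). Too few targets moved, and too few were measured, to decide, and CYP1A1 also rose under SUV, which hold no plasma protein.

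DHRS3 and RARB, which retinoic acid induces, fell with the agents that hold phospholipid: under SUV by -2.10 and -1.36, under rHDL by -1.81 and -0.92 and under native HDL by -1.09 and -0.49, while under apoA-I they did not pass (-0.06 and 0.02). Lower retinoic acid signalling, for instance by uptake of retinoids from the medium into lipid, is a candidate explanation. The targets CYP26A1, CYP26B1 and STRA6 did not pass under SUV (-0.04, -0.12 and -0.09), rHDL (-0.03, -0.20 and -0.06) or native HDL (-0.08, -0.14 and -0.07). This cannot decide the question, since the centred values hold no levels and a gene that is not expressed could not fall. Of 9 targets measured whose values had not been seen, 4 were lower under SUV (RARRES1, TGM2, RAI14 and NRIP1; median of the 9 -0.218), 5 under rHDL (median -0.27), 3 under native HDL (median -0.17) and 1 under apoA-I (NRIP1; median -0.00331). The bound set for the hypothesis concerned SUV, where fewer targets were lower than it asked for and more than its absence allows, so that it remains open. Retinoid content was not measured.

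Metallothionein genes had a list median under rHDL of -0.184 in the arrays without the prefix (adjusted p = 0.0151) and 0.377 in those with it (adjusted p = 0.000532), and 0.0286 on all arrays (adjusted p = 0.914). Under apoA-I it was -0.0422 without the prefix and 0.366 with it (adjusted p = 0.362 and 0.00558 by camera). Within the prefix set replicate 4 stood above replicate 5 under both agents, with array values of 0.448 and 0.0604 for rHDL and 0.439 and 0.089 for apoA-I. Across the groups 1128 genes were higher and 1363 lower in the arrays with the prefix. The first component of the residuals held 36.9% of their variance, and the olfactory receptor medians were highest in apoA-I replicate 4 (0.297) and rHDL replicate 4 (0.21). No 2 arrays were copies: the highest correlation within a group was 0.661 and the lowest median absolute difference of any 2 arrays was 0.0792.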
